A study of Canis lupus familiaris with 23 samples.

How the data were processed

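RNA abundance was measured by CEL-seq2, a bulk method that counts transcripts from their 3′ ends with barcoded primers, in 23 dog libraries of 12 groups: 6 tissue libraries, 11 libraries of organoids in expansion medium and 6 of organoids in differentiation medium. The deposited values are counts per gene, some with a fraction, and were treated like expected counts, in which a read can be shared between genes. The origin of the fractions was not tested. The submitters' processing notes name the aligner BWA 0.6.2-r126 and the dog build CanFam3.1. The gene annotation, the counting tool and whether reads with the same molecular barcode were collapsed are not given in the sources used here. Between 4.91 and 10.65% of the gene lines of a library held a fraction. The separate values of near-identical gene copies, such as the H2A histones, keratins and keratin-associated proteins, were treated as uncertain. The files name genes by symbol, and no gene coordinates were used.

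The 17 tissue and expansion libraries list 20448 entries and the 6 differentiation libraries list 18113, with 17141 in both. Counts were rounded to whole numbers. Of all entries, 20 had symbols turned into calendar dates by a spreadsheet and 4 named no gene. The entries without a gene held 0.461 to 2.158% of a library's counts and were left out. A reference table of dog gene symbols gave current symbols to 401 of 6665 entries with provisional locus names.

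Total counts ran from 86301 to 4822410 per library. A gene with a count of 0 in the deepest library could stand at up to 0.626 CPM (counts scaled to a fixed library total; 3 counts of the total), against 35.5 CPM in the shallowest. These floors cover counting error only. Lower bounds on folds against a group at 0 use the same 3 counts over the whole group. They are approximate, since these floors use unscaled totals and the level on the other side is scaled by TMM.

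Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed by the tool's default filter on the 12 groups, which left 9888 genes. Comparisons with differentiation libraries used the 9732 of these that those libraries list. Libraries were scaled by the trimmed mean of M values (TMM). A quasi-likelihood model with a mean for each of the 12 groups had 11 residual degrees of freedom, a common dispersion of 0.0986 and a prior of 10 degrees of freedom. A comparison of pooled groups took the plain mean of their log2 means. P-values were adjusted by Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. The SE of a log2 change is its size divided by the square root of the F statistic. The p-values rest on the spread between libraries within groups, pooled over the groups with replicates. The labels do not say whether replicates come from different dogs, cultures or preparations. Each interfollicular organoid group has 1 library and adds nothing to that spread, so p-values for these organoids assume that they vary like the other groups.

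The 15 comparisons set follicle, interfollicular epidermis and whole skin against each other, organoids against their tissue of origin, cultures with against cultures without the Tgf-beta inhibitor, pooled and at each passage, later against earlier passage, the inhibitor's effect at later against earlier passage, interfollicular against follicular organoids, and the differentiation media against expansion medium and each other. The groups, the comparisons, the gene lists, the naming rule and the alternatives listed are choices made before the data were examined.

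The 29 gene lists hold 686 genes, of which 605 are in the files. They cover basal keratinocytes and hemidesmosomes, keratinocyte differentiation and the cornified envelope, the epidermal lipid barrier, follicle stem cells and the outer root sheath, the hair shaft and inner root sheath, fibroblasts and dermal papilla, endothelium, smooth muscle and pericytes, immune cells, melanocytes, sebaceous gland, sweat and simple epithelium, adipocytes, Schwann cells, Tgf-beta targets, epithelial to mesenchymal transition, S phase, G2 and mitosis, Wnt and R-spondin targets, BMP targets, cAMP targets, Notch targets, wound and hyperproliferation keratins and alarmins, inflammatory cytokines, immediate early and heat shock genes, interferon response, cholesterol synthesis, glycolysis and hypoxia, and mitochondrially encoded genes. Some genes stand in more than a single list. Each list with at least 5 tested members was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Camera asks whether a list moved relative to all other genes.

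Named genes are the 5 largest called rises and falls with a symbol, at least 20 CPM on the higher side and no overlap between libraries, up to 4 called genes with the smallest p in each direction of each list (up to 2 by p where none was called), and a fixed set: KRT5, KRT14, KRT1, KRT10, KRT15, KRT17, SOX9, LGR5, LGR6, CD34, TP63, FLG, LOR, IVL, MKI67, VIM and COL1A1, with TGFBI and SMAD7 among those for the inhibitor and AXIN2, ID1, ID3, CREM and NR4A1 for differentiation. Provisional locus names, open reading frame names and date-like symbols were passed over among the largest changes. No fold is given for genes with 1 to 3 counts on a side, which includes most values of KRT1, SOX9 and LGR5. LGR6, MKI67, SMAD7 and ID3 were not among the genes tested. Metalloproteinases, cyclin-dependent kinase inhibitors and the signal peptidase and translocon genes were chosen after their values were seen.

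The procedure was tested on simulated data with the same groups, depths and dispersion, in which 200 genes were changed 2-fold, 4-fold or 8-fold. Alternatives were the DESeq2 1.42.0 Wald test, limma voom, DESeq2 size factors or library totals in place of TMM, no filter or a filter of 10 CPM in 2 libraries, a fit to the compared groups alone, counts thinned to the smallest library with seed 11, a test against a 1.5-fold change, the replicate number as a block over all groups or within each kind of sample, and each replicate left out in turn. Alternatives by passage and without genes at a carry-over level were added after seeing the data. That level is 3 times a gene's tissue level times the share of tissue hair transcripts, averaged over the compared expansion groups. Tissue level, here and below, is the mean CPM over the follicle and whole skin libraries. A library's share is the median over the hair-list genes with at least 100 counts in those tissues. Genes of any count were held against the level. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.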

Results

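The data describe dog skin, hair follicles and epidermis, and epidermal organoids grown from them, across 23 libraries in 12 groups. Tissue gave 2 libraries of whole skin, 2 of hair follicles mixed from growing and resting phases, and 2 of interfollicular epidermis. Organoids in expansion medium were taken at day 7, either at passages 0 to 1 (early) or 3 to 6 (later). Follicle-derived organoids with a Tgf-beta inhibitor gave 3 early and 2 later libraries, and those without it 2 early and 2 later ones. Interfollicular organoids, all with the inhibitor, gave 1 early and 1 later library, so neither of these groups has a replicate. Later follicle-derived organoids were also moved to differentiation medium, with 2 libraries each in that medium, in the medium without Noggin and R-Spondin-1, and in the medium that also lacked Forskolin. Noggin blocks BMP signals, R-Spondin-1 raises Wnt signalling, and Forskolin raises cAMP.

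Total counts per library lay between 461780 and 1378031 in whole skin, 712593 and 1519680 in follicles, and 86301 and 335949 in interfollicular epidermis. With the inhibitor, follicle-derived organoids had 1790293 to 4822410 counts early and 1095813 to 1500100 later, and interfollicular ones 474823 early and 222051 later. Without it, the totals were 734647 to 2340121 early and 2546895 to 3563373 later. Differentiation medium gave 296781 to 694104, its version without Noggin and R-Spondin-1 409603 to 435222, and that also without Forskolin 237864 to 473004. Mitochondrially encoded transcripts took from 5.35% of counts in replicate 1 to 26.9% in replicate 2 of the early inhibitor group. Changes are given as log2 fold changes ± SE from edgeR, with levels as the mean CPM of the groups on each side, each group being the mean of its libraries. The first 2 principal components of 5042 genes held 41.1% and 16.9% of the variance.

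**Figure D1:**
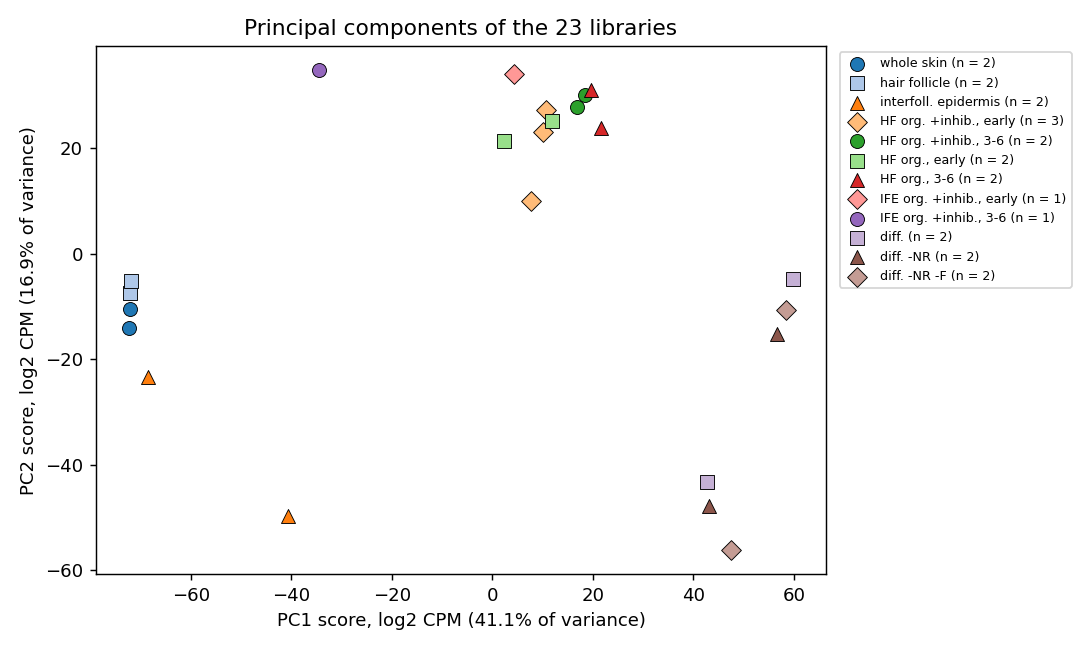
Scores of the 23 libraries on the first (x axis) and second (y axis) principal component of log2 CPM, with a point per library and a colour and shape per group. Tissue lies at PC1 scores of -72.3 to -40.6, follicle-derived organoids in expansion medium at 2.35 to 21.7, differentiation medium at 42.8 to 59.8, and the later interfollicular organoid library apart from the others at -34.5.

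Hair follicles were compared with interfollicular epidermis to ask how the source tissues differ. Follicles held far more hair-shaft keratin: KRT32 was higher by 4.54 ± 0.53 (1557 against 57.6 CPM, adjusted p = 0.000162) and KRT33B by 4.39 ± 0.54 (1523 against 62.5 CPM). LHX2, a transcription factor of follicle stem and germ cells, was higher by 3.43 ± 0.63 (186.0 against 12.2 CPM, adjusted p = 0.00444). Epidermis held more of the suprabasal differentiation genes KRT10 (-4.02 ± 0.71, 668.1 against 10826 CPM), DSC1, a desmosomal cadherin (-3.44 ± 0.71), and SCEL, a cornified envelope protein (-2.99 ± 0.53). The basal keratins did not pass the test: KRT5 stood at 4933 against 4908 CPM and KRT14 at a change of -0.67 (adjusted p = 0.558). KRT10 was not called without follicle replicate 1 (-3.80), nor SCEL without epidermis replicate 1 (-2.63).

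In the hair shaft and inner root sheath list, 26 of 34 tested members rose in follicles and 0 fell (29 rose and 1 fell adjusted over the list alone), with a median of 3.76, or 3.51 with members at 0 on a side set to their bound (camera adjusted p = 5.87e-47, and 0.000818 with an estimated correlation). The hair keratins KRT81 (4.51 ± 0.55) and KRT74 (4.79 ± 0.60) were among them, while KRT36 and PADI3, an enzyme that hardens hair, were at least 6.53-fold and 5.14-fold higher against 0 counts in epidermis. Of the adipocyte list 4 of 8 rose (8 adjusted over the list alone, camera adjusted p = 9.28e-09 and 0.00553 estimated), among them PLIN1, which coats fat droplets, and the fat hormone ADIPOQ (2.95), and of the sweat and simple epithelium list 4 of 9 rose (6 rose and 1 fell adjusted over the list alone, 0.000413 and 0.0228), among them KRT8 (4.24 ± 0.63) and KRT7 (2.62). PLIN4, another fat droplet protein, was at least 5.88-fold higher, HSF4, a heat shock factor, at least 3.75-fold, and LAMA2, a basement membrane laminin, at least 3.41-fold. SCUBE2, a secreted Hedgehog pathway protein, was lower in follicles (-4.35).

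Other lists were called by camera but lost the call with an estimated correlation. Of the keratinocyte differentiation list 5 of 36 fell and 0 rose (7 fell and 1 rose adjusted over the list alone, camera adjusted p = 2.03e-05, adjusted p = 0.359 with an estimated correlation). Of the sebaceous list 6 of 16 rose (10 adjusted over the list alone; 2.88e-07, adjusted p = 0.0931 with an estimated correlation), with the lipid enzymes ELOVL3 (3.73), FADS1 (3.38) and SCD (1.91). Of the fibroblast and dermal papilla list 5 of 22 rose (6 adjusted over the list alone; 3.52e-06, adjusted p = 0.107 with an estimated correlation), with the collagens COL6A1 (2.98) and COL1A1 (2.60 ± 0.63, 1418 against 219.9 CPM), which was not called without follicle replicate 1 (2.28) or 2 (2.90) or epidermis replicate 2 (1.94). Of the BMP target list 3 of 7 rose, namely BAMBI (3.16), ID2 (2.33) and the ligand BMP4 (2.90), with an adjusted p of 0.00737, or 0.105 with an estimated correlation. Of the immune list 2 of 10 fell (4 adjusted over the list alone; 4.19e-05, adjusted p = 0.121 with an estimated correlation), the antigen presentation genes DLA-DRA (-2.54 ± 0.47) and CD74 (-1.95 ± 0.50), so epidermis held more of them. The follicle stem cell list had 1 of 20 higher (0.00737, adjusted p = 0.166 with an estimated correlation) and the melanocyte list 1 of 5 (0.000413, adjusted p = 0.163 with an estimated correlation).

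In all, 203 genes were higher and 73 lower in follicles, of 9888 tested, and 6 of the 43 called genes that the naming rule took kept their call in every setting run. The count rests on each library: without follicle replicate 1 or 2 it was 149 or 113, and without epidermis replicate 1 or 2 it was 147 or 170. Scaling to library totals moved the median of all genes from 0.21 to -0.10 and the split to 146 higher and 143 lower. On simulated data the comparison recovered 0% of 2-fold, 28.4% of 4-fold and 60.6% of 8-fold changes.

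Whole skin was set against its parts to see which transcripts the isolation removed. Isolated follicles and whole skin differed in 0 genes by edgeR, with 144 at an unadjusted p under 0.05, and in 0 genes by DESeq2 and by voom. A fit to these groups alone called 10 genes. By value, KRT10 stood at 668.1 CPM in follicles against 2217 in skin and CD74 at 148.1 against 474.5, both with an adjusted p of 1. Camera placed the hair list higher (median 0.49, adjusted p = 4.66e-10, adjusted p = 0.426 with an estimated correlation) and the immune list lower in follicles (median -0.83, 1.95e-05, adjusted p = 0.426 with an estimated correlation), with 0 of their members called. Simulated 4-fold and 8-fold changes were recovered in 38.8% and 68.2% of cases.

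Interfollicular epidermis was set against whole skin. KRT32 (-3.80 ± 0.52, 57.6 against 934.8 CPM, adjusted p = 0.00126), KRT86 (-3.96), LHX2 (-3.20) and PLIN1 (-4.05) fell, and PLIN4 was at least 7.65-fold and the basement membrane collagen COL4A2 at least 6.52-fold lower. Higher in epidermis were SCEL (2.58 ± 0.53, 198.3 against 34.6 CPM), the transcription factor IKZF2 (2.73) and the protease inhibitor SERPINB7 (2.47). In the hair list 23 of 34 fell and 0 rose (29 fell and 1 rose adjusted over the list alone, camera adjusted p = 6.01e-43, and 0.000675 estimated). The adipocyte list had 5 of 8 lower (8.49e-13 and 0.000675 estimated), the sebaceous list 5 of 16 (4.17e-09 and 0.0419 estimated), with ELOVL3 (-3.93), and the sweat list 2 of 9 (0.00168 and 0.0346 estimated), with KRT8 (-3.56). In the differentiation list 1 of 36 rose (5 adjusted over the list alone, 0.000433, adjusted p = 0.466 with an estimated correlation), and KRT10 at 2.29 did not pass (adjusted p = 0.098). The smooth muscle list had 2 of 9 lower (4.98e-05, adjusted p = 0.0995 with an estimated correlation), MYH11 (-2.07) and ACTG2 (-1.81), and the fibroblast list 2 of 22 (4.98e-05, adjusted p = 0.147 with an estimated correlation), COL6A1 (-2.87) and DPT (-2.90). SCEL was not called without epidermis replicate 1 (2.21) or either skin replicate (2.41 and 2.71), and 5 of 29 named genes kept their call in every setting run. The comparison called 16 genes higher and 138 lower, or 87 and 64 genes without skin replicate 1 and 2 and 76 without epidermis replicate 2. By library totals the split was 35 higher and 107 lower, with a median of all genes of 0.03 in place of -0.20. It recovered 20.9% of simulated 4-fold and 54.5% of 8-fold changes.

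Follicle-derived organoids in expansion medium (9 libraries) were compared with follicle tissue (2) to ask what the cultures keep. Among basal keratinocyte genes, KRT14 was higher by 2.90 ± 0.49 (28625 against 3807 CPM, adjusted p = 0.000103) and KRT5 by 2.76 ± 0.51, with the hemidesmosome collagen COL17A1 (2.80 ± 0.45) and the laminin-binding integrins ITGA3 (2.79) and ITGA6 (1.94). Transcripts of other skin cells and of the hair shaft fell, with the fibroblast genes DCN at -5.66 ± 0.29 (42.4 against 1365 CPM) and COL1A1 at -6.32 ± 0.41, MYH11 of smooth muscle at -6.34 ± 0.28, and KRT32 at -6.81 (13.9 against 1557 CPM). LHX2 (-5.63 ± 0.35) and CD34, a follicle bulge marker (-5.94 ± 0.46), fell, and LGR5, a stem cell receptor, had 3 counts in the organoid libraries against 19 in tissue. CD34 was not particular to follicles in these tissues, at 44.7 CPM there, 45.9 in whole skin and 14.8 in interfollicular epidermis. KRT15, a basal and bulge keratin, did not pass the test (-0.67, adjusted p = 0.498), nor did TP63, the master regulator of basal keratinocytes (0.81, adjusted p = 0.101), KRT17 (0.24) or IVL (0.45).

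Every tested member of the fibroblast (22), endothelial (9), smooth muscle (9), melanocyte (5) and Schwann (4) lists fell, as did 33 of 34 of the hair list, 9 of 10 of the immune, 7 of 9 of the sweat, 7 of 8 of the adipocyte and 14 of 16 of the sebaceous list, in which 1 rose. Camera adjusted p was 3.17e-19, 1.81e-07, 2.03e-10, 6.22e-06, 1.02e-41, 6.61e-07, 7.84e-08, 3.33e-09 and 1.18e-06 for these apart from the Schwann list, which had too few members. The calls held with an estimated correlation except for the melanocyte (adjusted p = 0.0584) and sebaceous lists (adjusted p = 0.092). In the Wnt target list 8 of 15 fell (9 fell and 1 rose adjusted over the list alone; 0.000277, and 0.0308 estimated), with APCDD1 (-5.54) and LEF1 (-5.30), in the BMP target list 6 of 7 (6.79e-05, and 0.0308 estimated), with BAMBI (-5.07) and ID2 (-2.81), and in the epithelial to mesenchymal transition list 10 of 14 fell and 1, SNAI2, rose (1.67e-06, and 0.0308 estimated). In the follicle stem cell list 11 of 20 fell and 2 rose (12 and 2 adjusted over the list alone; 0.00107, adjusted p = 0.092 with an estimated correlation). DKK3 (2.14) and PHLDA1 (2.27) rose, and KRT75 (-5.06) fell.

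Several lists with risen members were called by camera but lost the call with an estimated correlation. Of the glycolysis and hypoxia list 21 of 25 rose and 0 fell (camera adjusted p = 2.39e-09, adjusted p = 0.155 with an estimated correlation), among them the glucose transporter SLC2A1 (4.11 ± 0.65, 875.0 against 49.4 CPM) and the glycolytic enzymes ENO1 (3.25) and GAPDH (2.48). Of the G2 and mitosis list 10 of 28 rose (14 adjusted over the list alone; 2.89e-05, adjusted p = 0.372 with an estimated correlation), with CDC20, an activator of anaphase, at 2.78, and of the S phase list 5 of 25 (0.00107, adjusted p = 0.486 with an estimated correlation). Of the cholesterol list 10 of 22 rose and 1 fell (12 and 1 adjusted over the list alone; 2.89e-05, adjusted p = 0.212 with an estimated correlation), with SQLE (2.12) and CYP51A1 (1.91). Of the wound list 8 of 15 rose (0.000446, adjusted p = 0.28 with an estimated correlation), with the alarmin S100A8 (4.13 ± 0.78), KRT6A (2.58) and FOSL1 (3.36), and of the inflammatory list 4 of 6 (0.0119, adjusted p = 0.25 with an estimated correlation), with PTGS2 (3.06) and IL1A (2.37). The basal list had 10 of 17 higher and 1 lower, DST (-1.23), with an adjusted p of 0.000186, or 0.092 with an estimated correlation.

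Of the keratinocyte differentiation list 16 of 36 fell and 1, KRT10 (1.56 ± 0.56, 2978 against 668.1 CPM), rose (18 fell and 2 rose adjusted over the list alone; 0.00672, adjusted p = 0.534 with an estimated correlation). KRT10 was not called under either other scaling or without either tissue replicate (1.35 and 1.84). The barrier proteins FLG (-3.26 ± 0.69), TGM3 (-5.27) and KRT80 (-4.34) fell. In the lipid barrier list 6 of 17 fell (adjusted p = 0.0985), with the ceramidase ACER1 at -4.97. Of the Tgf-beta target list 6 of 34 rose and 9 fell (8 and 10 adjusted over the list alone; median -0.25, adjusted p = 0.615), with THBS1 (-4.12) and CTGF (-5.44) lower. The cAMP list had 1 of 18 higher and 7 lower (0.196), the Notch list 1 and 1 of 8, the interferon list 0 and 3 of 12 (0.762), and the immediate early and heat shock list 3 and 3 of 18 (0.554), with HSPA8, a chaperone, at 1.56 and NR4A1 at -2.19. Of the mitochondrially encoded list 2 of 13 rose (1 adjusted over the list alone; 0.0231, adjusted p = 0.555 with an estimated correlation).

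The comparison called 891 genes higher and 1875 lower, 1643 in all without tissue replicate 1 and 1389 without replicate 2, and 89 of 130 named genes kept their call in every setting run. By DESeq2 size factors the split was 615 and 2179 and by library totals 594 and 2219, as the median of all genes moved from 0.00 to -0.17 and -0.19. Simulated changes were recovered in 14.9% (2-fold), 73.1% (4-fold) and 89.4% (8-fold) of cases.

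Interfollicular organoids (1 early and 1 later library) were set against interfollicular tissue. KRT10 (-4.32 ± 0.73, 712.7 against 10826 CPM, adjusted p = 0.000495), DSG1, a suprabasal desmosomal cadherin (-3.30 ± 0.53), SCEL (-3.80) and FLG (-4.26 ± 1.24) fell. SLC2A1 was higher by 4.76 ± 0.81 (910.3 against 29.0 CPM), the wound keratins KRT16 by 3.35 and KRT6A by 2.92, and CDH3, the basal P-cadherin, by 3.05 ± 0.52 (563.2 against 71.1 CPM). KRT5 rose by 1.70 ± 0.55 (adjusted p = 0.0483), though not under size factors (1.51), under library totals or without tissue replicate 1 (1.11), whereas KRT14 (1.52, 0.0624), KRT17 (1.87, 0.0607), IVL (3.20, 0.0794) and LOR (-4.46, 0.0688) did not pass.

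Of the differentiation list 9 of 36 fell (19 fell and 1 rose adjusted over the list alone; camera adjusted p = 3.28e-09, adjusted p = 0.464 with an estimated correlation), of the glycolysis list 13 of 25 rose (16 adjusted over the list alone; 1.34e-11, adjusted p = 0.399 with an estimated correlation), with PFKP (3.42), and of the wound list 6 of 15 rose (7 rose and 1 fell adjusted over the list alone; 0.0059, adjusted p = 0.622 with an estimated correlation), with S100A8 (3.98) and FOSL1, at least 10.2-fold higher. Some markers of other cells were lower: 5 of 22 fibroblast genes (10 adjusted over the list alone; 2.93e-05, adjusted p = 0.399 with an estimated correlation), with DCN at -3.64 ± 0.49, 4 of 10 immune genes (3.67e-05, adjusted p = 0.389 with an estimated correlation), with CD74 at -4.41, and 3 of 9 smooth muscle genes (7.71e-05, adjusted p = 0.389 with an estimated correlation). The later organoid library held markers of other cells at a median of 13% of their level in skin and follicle tissue. The early one held them at 3.9% of it. Interfollicular tissue is not part of that level. DCN was at -2.25 with the later and -5.04 with the early library alone. Of the Notch list 3 of 8 rose, the ligands JAG2 (2.62) and DLL1 (at least 7.14-fold) and the feedback gene NRARP (1.62), and HEYL was at least 4.01-fold lower, while the list's median (-0.02) and mean (0.10) differed in sign (0.775). The basal list had 3 of 17 higher and 1 lower (0.088), with a median of 0.58 that was -0.02 by library totals. The G2 list had 2 of 28 higher (0 adjusted over the list alone; 0.00575, adjusted p = 0.726 with an estimated correlation). At the extremes, the clock gene ARNTL was at least 20.4-fold higher and SERPINA12, a secreted protease inhibitor, at least 35.6-fold lower.

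The comparison called 665 genes higher and 445 lower, 416 in all without tissue replicate 1 and 709 with the early organoid library alone, and 22 of 60 named genes kept their call in every setting run. By library totals the split was 389 and 1111 and the median of all genes -0.70 in place of -0.14. Simulated changes were recovered in 13.4% (4-fold) and 47.0% (8-fold) of cases.

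The Tgf-beta inhibitor was tested in follicle-derived organoids, 5 libraries with it against 4 without. Single genes changed strongly, while each list that camera called lost the call with an estimated correlation. RGS2, a brake on G protein signals, rose by 4.99 ± 0.36 (261.3 against 6.91 CPM, adjusted p = 3.77e-08), TIMP1, a metalloproteinase inhibitor, by 3.95 ± 0.38 (2671 against 172.8 CPM) and IVL, a cornified envelope protein, by 3.22 ± 0.79 (6501 against 752.7 CPM, adjusted p = 0.0299). PMEPA1, a feedback target of Tgf-beta (-3.94 ± 0.49, 2.19 against 32.8 CPM, adjusted p = 0.000139), and COL7A1, the anchoring fibril collagen (-2.98 ± 0.41, 9.96 against 80.4 CPM), fell. KRT10 fell as well (-2.24 ± 0.44, 909.1 against 5046 CPM, adjusted p = 0.00576), in contrast to IVL. KRT5 (-0.04) and KRT14 (-0.20) did not pass. RGS2 and COL7A1 kept their call in every setting run, but KRT10 was not called without early replicate 1 lacking the inhibitor (-1.38) or later replicate 1 with it (-2.09).

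Of the differentiation list 7 of 36 rose and 1, KRT10, fell (15 and 2 adjusted over the list alone; median 1.52, camera adjusted p = 1.78e-06, adjusted p = 0.499 with an estimated correlation), with CNFN, a cornified envelope protein (4.06 ± 0.76), the crosslinking enzyme TGM1 (3.56) and the transcription factors PRDM1 (2.09) and OVOL1 (1.35). Of the lipid barrier list 4 of 17 rose (9 adjusted over the list alone; 2.26e-06, adjusted p = 0.34 with an estimated correlation), among them the lipoxygenase ALOX12B (4.81) and SDR9C7 (3.65). Of the wound list 4 of 15 rose (6 adjusted over the list alone; 8.71e-07, adjusted p = 0.34 with an estimated correlation), with SERPINB2 (3.28) and S100A9 (2.33), of the inflammatory list 3 of 6 (5 adjusted over the list alone; 1.28e-05, adjusted p = 0.34 with an estimated correlation), namely IL1A (2.28), IL18 (2.24) and the neutrophil chemokine CXCL8 (3.23), and of the glycolysis list 4 of 25 (13 adjusted over the list alone; 9.89e-09, adjusted p = 0.34 with an estimated correlation), with VEGFA (2.04) and EGLN3 (3.05). In early replicate 1 with the inhibitor IVL stood at 24318 CPM and in the other 4 libraries with it at 1675 to 4311 CPM. IVL was not called without that library (2.19), nor without 5 of the other libraries left out in turn (2.84 to 3.40).

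Of the Tgf-beta target list 3 of 34 fell, PMEPA1, FN1 (-2.10) and ID1 (-1.40) (8 fell and 1 rose adjusted over the list alone; 0.0111, adjusted p = 0.499 with an estimated correlation), while TGFBI (-1.91, adjusted p = 0.0619) did not pass. Of the fibroblast list 3 of 22 fell (0.000608, adjusted p = 0.355 with an estimated correlation), COL5A1 (-2.37), VIM (-1.53) and DCN (-1.26), the latter 2 with overlapping libraries, and of the epithelial to mesenchymal transition list 2 of 14 (6 adjusted over the list alone; 0.00157, adjusted p = 0.34 with an estimated correlation), FN1 and VIM. VIM and DCN fell at early passage (-2.83 and -2.51), while at later passage VIM stood at -0.23 and both had an adjusted p of 1, and neither passed the interaction (adjusted p = 1 and 0.981). VIM was not called without early replicate 1 lacking the inhibitor (-0.80) or 4 of the other libraries in turn (-1.72 to -1.39), and DCN without 8 of the 9 in turn (-1.33 to -1.21). That early library held markers of other cells at a median of 4.93%, and melanocyte markers at 15.2%, of the tissue level, against 2.39% and 1.19% in replicate 2. The S phase and G2 lists lay lower (medians -0.72 and -0.31, 1.28e-05 and 0.0164) with 0 members called and adjusted p = 0.507 and 0.687 with an estimated correlation. The cAMP list had 2 of 18 higher (4 adjusted over the list alone; 0.0111, adjusted p = 0.34 with an estimated correlation), with the growth factor AREG at 1.70. In the BMP list ID2 rose (1.58) and ID1 fell, and its median (-0.44) and mean (0.11) differed in sign (0.908).

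**Figure D2:**
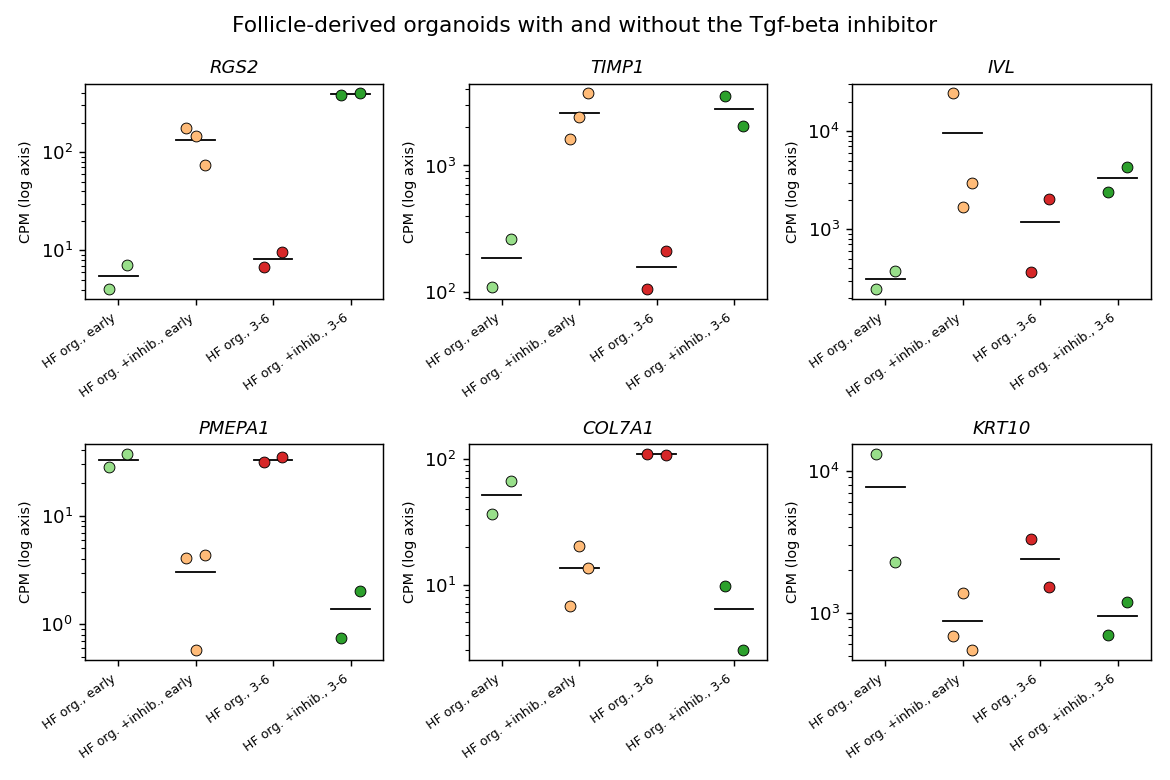
CPM (log y axis) of 6 genes in follicle-derived organoids without and with the Tgf-beta inhibitor, early and at passages 3 to 6 (x axis), with a point per library and a line at each group mean. RGS2 and TIMP1 lie higher, and PMEPA1, COL7A1 and KRT10 lower, in all 5 libraries with the inhibitor than in the 4 without it, while IVL overlaps.

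The pooled comparison called 190 genes higher and 75 lower, and 8 of 38 named genes kept their call in every setting run. Without early replicate 1 or 2 of the cultures lacking the inhibitor it called 119 or 165, without later replicate 1 or 2 of them 120 or 168, and without later replicate 1 or 2 with the inhibitor 109 or 148. By library totals the split was 133 and 116, and the median of all genes moved from 0.00 to -0.13. Simulated 2-fold, 4-fold and 8-fold changes were recovered in 25.4%, 73.1% and 89.4% of cases.

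At early passage alone (3 against 2 libraries) the inhibitor comparison called 84 genes higher and 45 lower, and at later passage (2 against 2) 19 and 12. Early, CXCL8 rose by 5.58, CNFN by 5.50, IVL by 4.95 (9652 against 310.9 CPM, adjusted p = 0.0474) and SERPINB2 by 4.70, while CXCL14, an epithelial chemokine (-4.91, 88.8 against 2676 CPM, adjusted p = 0.000942), and KRT10 (-3.14, 871.9 against 7694 CPM) fell. In early replicate 1 without the inhibitor KRT10 stood at 13104 CPM against 2284 in replicate 2, and the pigment cell gene TYRP1, which was called lower with the inhibitor (-4.13), at 229 against 5.73, and without that library the changes were 0.14 for TYRP1 and -1.41 for KRT10, neither called. IVL was not called without early replicate 1 with the inhibitor (2.87) or either replicate lacking it (4.66 and 5.25). Later, RGS2 rose by 5.56 (390.9 against 8.27 CPM, adjusted p = 3.27e-06) and TIMP1 by 4.13 (2775 against 158.8 CPM), and COL7A1 (-4.01), FST (-3.11) and COL5A1 (-2.70) fell. The early wound list had 4 of 15 higher (10 adjusted over the list alone; 6.45e-08, adjusted p = 0.292 with an estimated correlation) and the later glycolysis list moved up (2.04e-06, adjusted p = 0.628 with an estimated correlation) with 0 of 25 called. The early count fell to 55 and 71 without replicates 1 and 3 with the inhibitor and to 9 and 35 without replicates 1 and 2 lacking it, and by library totals its split was 48 and 67, with a median of all genes of -0.17. Of the named genes 0 of 31 early and 2 of 11 later, RGS2 and TIMP1, kept their call in every setting run. The later count fell to 6 and 3 without replicates 1 and 2 with the inhibitor and to 11 without either replicate lacking it. Simulated 4-fold changes were recovered in 61.2% of cases early and 52.2% later.

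Whether the effect of the inhibitor differed between passages was tested by the interaction. It called 0 genes by edgeR (267 at an unadjusted p under 0.05, smallest adjusted p 0.481), 1 by DESeq2 and 0 by voom. Simulated 4-fold and 8-fold differences were recovered in 20.9% and 56.1% of cases. Camera found 6 lists that differed, of which none kept the call with an estimated correlation. The inhibitor's effect at later passage was less positive for the inflammatory list (median difference -1.68, adjusted p = 2.12e-06, adjusted p = 0.226 with an estimated correlation) and the wound list (-2.18, 1.4e-05, adjusted p = 0.604 with an estimated correlation).

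Later passage was compared with early passage over the same 9 follicle-derived libraries to ask how the cultures change with time. The fibroblast transcripts DCN (-1.79) and COL3A1 (-2.65) fell. Without early replicate 1 lacking the inhibitor, which held markers of other cells at 4.93% and of melanocytes at 15.2% of the tissue level, COL3A1 was not called (-2.01). With any later library left out in turn neither was called (DCN -1.85 to -1.74, COL3A1 -2.74 to -2.56), nor was DCN without early replicate 3 with the inhibitor (-1.69). TYRP1 was lower too (-1.91) but did not pass (adjusted p = 0.509). GLI2, a Hedgehog pathway transcription factor (-4.62), and IRX4, a homeobox factor (-4.29 ± 0.53, 3.37 against 61.6 CPM, adjusted p = 0.000589), fell too. Higher were CCND2, a cyclin of G1 phase (1.25, 1073 against 444.6 CPM), the growth factor NRG1 (1.37), and KRT4, a keratin of mucosal epithelium (4.62 ± 0.84, 45.8 against 1.18 CPM, with overlapping libraries), which was not called without early replicate 2 (3.98) or later replicate 2 (3.89) lacking the inhibitor or early replicate 3 (4.40) or later replicate 2 (2.85) with it. Of the fibroblast list 3 of 22 fell (8 fell and 1 rose adjusted over the list alone; median -1.15, camera adjusted p = 6.73e-06, adjusted p = 0.367 with an estimated correlation), and of the immediate early list 1 of 18, EGR2 (-2.12; 6.73e-06, adjusted p = 0.367 with an estimated correlation). The differentiation list lay lower (median -0.80, 0.000465, adjusted p = 0.785 with an estimated correlation), although its only called member rose, and the basal list lay higher (0.37, 0.00221, adjusted p = 0.367 with an estimated correlation) with 0 of 17 called. The Wnt list had 0 of 15 called (1 rose and 2 fell adjusted over the list alone; 0.0105, adjusted p = 0.367 with an estimated correlation).

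The passage comparison called 17 genes higher and 18 lower and depends on single libraries, and 0 of 13 named genes kept their call in every setting run. With the inhibitor the count was 53 and 17 without early replicates 1 and 3 and 9 without either later replicate. In cultures lacking it the count was 20 and 18 without early replicates 1 and 2 and 23 and 11 without later replicates 1 and 2. Simulated 2-fold and 4-fold changes were recovered in 31.3% and 76.1% of cases.

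Interfollicular organoids (2 libraries) were compared with follicle-derived organoids with the inhibitor (5) to ask whether the cultures keep traces of their source. Higher in the interfollicular ones were the hair keratins KRT32 by 2.73 ± 0.41 (134.4 against 15.8 CPM, adjusted p = 0.000159), KRT85 by 2.74 and KRT33B by 2.34, opposite to the source tissues. KLF4, a transcription factor of suprabasal keratinocytes, was higher by 2.83 ± 0.28 (424.7 against 51.0 CPM, adjusted p = 3.95e-07), the tubulin TUBA8 by 8.38 (98.5 against 0.325 CPM), and the Notch genes DLL1 by 3.14 and NRARP by 1.44. HBEGF, an EGF receptor ligand, was lower (-1.62), but not called without early replicate 3 (-1.59) or later replicate 1 (-1.44) of the follicle-derived organoids, while KRT5 (-1.06, adjusted p = 0.262) and KRT14 (-0.61) did not pass. In the hair list 16 of 34 rose (19 adjusted over the list alone; camera adjusted p = 1.76e-11, adjusted p = 0.844 with an estimated correlation). The list summed to 3667 CPM in the later and 913.4 in the early interfollicular library and to 318.9 to 458.3 in the 9 follicle-derived expansion libraries, that is, a median of 12.4%, 2.3% and 0.704 to 1.26% of the level in skin and follicle tissue.

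Of the fibroblast list 3 of 22 rose (5 adjusted over the list alone; 0.00904, adjusted p = 0.844 with an estimated correlation), with DCN (2.40, 138.8 against 17.6 CPM) and COL1A1 (2.15, with overlapping libraries), which was not called without either later follicle-derived replicate (2.14 and 2.22) or with early libraries alone (0.18), and 1 of 9 smooth muscle genes, ACTA2, was higher (3.17). Of the 10 immune genes 1 rose, while 0 of the endothelial, melanocyte, adipocyte and Schwann genes were called. Of the cholesterol list 1 of 22 fell, CYP51A1 (-1.31; 0.00904, adjusted p = 0.844 with an estimated correlation). The Notch list had 2 of 8 higher, but its median (-0.36) was negative and camera placed it up (0.519). The histones HIST3H2A, H2AC11, H2AC15 and H2AC17 were each higher, with identical counts and an approximate bound of 203-fold. That bound is somewhat too high, as TMM scaling raises the floor of the follicle-derived libraries. In all 578 genes were higher and 51 lower, against 60 called when the early libraries were compared alone, and 2 of 28 named genes kept their call in every setting run. KLF4 did, whereas KRT32 was not called in the early libraries alone. By DESeq2 size factors the median of all genes moved from -0.33 to -0.14. Simulated 4-fold and 8-fold changes were recovered in 16.4% and 65.2% of cases.

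**Figure D3:**
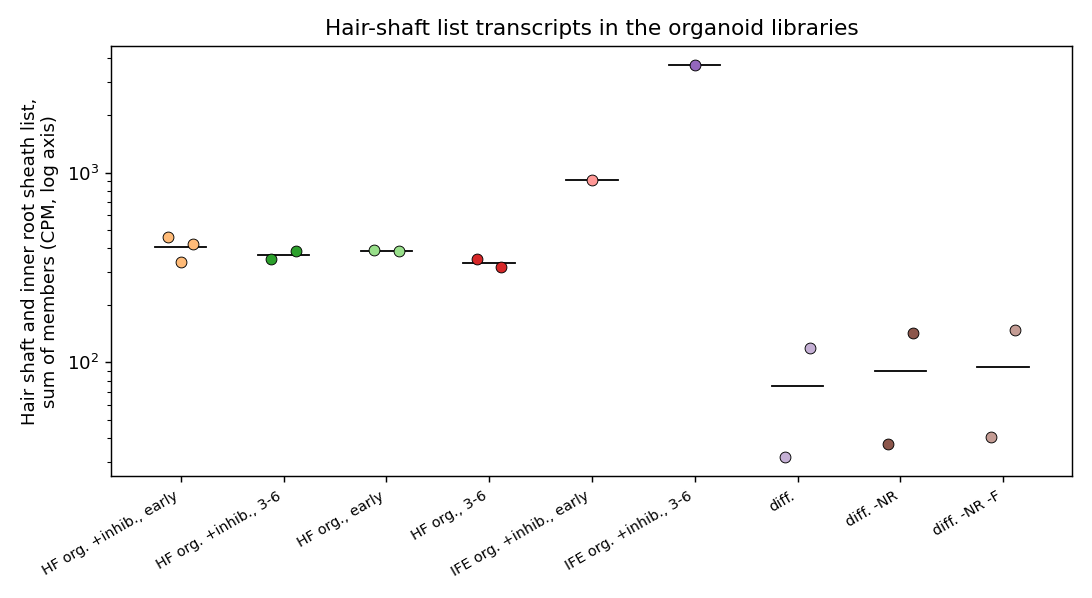
Summed CPM of the hair shaft and inner root sheath list (log y axis) in each organoid group (x axis), with a point per library and a line at the group mean. The later interfollicular library stands at 3667 CPM, the follicle-derived expansion libraries at 318.9 to 458.3 and the differentiation libraries at 31.9 to 148.4.

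Differentiation medium (2 libraries) was compared with expansion medium without the inhibitor at the same passages (2). Among the called genes, CLDN4, a tight junction protein, rose by 5.99 ± 0.79 (174.2 against 2.68 CPM, adjusted p = 0.000932), and the simple epithelial keratins KRT19 by 4.82 and KRT7 by 3.62. KRT80, a keratin of differentiating epithelium, rose by 4.70, ISG15, an interferon-induced modifier, by 5.16 (69.0 against 2.04 CPM, adjusted p = 0.00448) and the glycolytic enzyme PFKP by 2.20. KRT10 (-2.64, 382 against 2398 CPM, adjusted p = 0.0341), the tetraspanin CD9 (-2.48, 180.3 against 997.1 CPM), the desmosomal plaque protein DSP (-2.00) and the immediate early factor FOS (-4.46) fell. IVL (2.32, adjusted p = 0.257), FLG (3.43, 0.114), LOR (3.93, 0.154), KRT5 (-1.27, 0.194) and KRT14 (0.06) did not pass. IVL stood at 1901 CPM in replicate 1 and 10051 in replicate 2. Without expansion replicate 1 neither KRT10 (-1.97) nor ISG15 (4.13) was called, and KRT10 was not without differentiation replicate 2 (-2.18).

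Of the sweat and simple epithelium list 2 of 8 rose (camera adjusted p = 0.0343, adjusted p = 0.573 with an estimated correlation), and of the interferon list 1 of 12 (2 adjusted over the list alone; 0.0128, adjusted p = 0.573 with an estimated correlation). The differentiation list had 2 of 36 higher and 2 lower (6 and 2 adjusted over the list alone; 0.208). The cholesterol, S phase and G2 lists lay lower (medians -0.53, -0.65 and -0.66) with 0 members called and adjusted p of 0.00676, 0.0343 and 0.00795, each 0.921 with an estimated correlation. Of the hair list 4 of 20 fell (8 adjusted over the list alone; 0.00676, adjusted p = 0.921 with an estimated correlation), with a median of -4.12 that was -0.99 with its 14 members at 0 set to their bound. KRTAP8-1, a hair matrix protein, was at least 21.7-fold, KRT34 at least 7.37-fold and DCN at least 4.72-fold lower. In expansion medium these 3 stood at the carry-over level, that is, within 3 times the share of tissue hair transcripts, of which the median over 30 genes was 0.892 and 0.989% there. Summed over the hair list, the 2 expansion libraries stood at 350.9 and 318.9 CPM and those in differentiation medium at 31.9 and 118.8. Genes that the differentiation libraries do not list enter these sums as 0. Part of the difference may thus be missing entries. Of the called genes 26 stood at that level, and 296 were called without genes at it. KLF4 was called lower, with 1 count in differentiation medium against 171 in the deeper expansion libraries. AXIN2, CREM and NR4A1 had 1 or 2 counts in differentiation medium against 30, 47 and 80 in those deeper libraries. None of them passed (adjusted p = 0.382, 0.317 and 0.356), nor did ID1 (-1.28).

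The comparison called 121 genes higher and 202 lower, but 29 and 96 in all without expansion replicate 1 and 2 and 12 without differentiation replicate 2, and 1 in a fit to these groups alone, and 0 of 26 named genes kept their call in every setting run. The differentiation libraries list another set of genes than the expansion libraries, so a difference in how they were processed cannot be separated from that of the medium. Simulated 4-fold and 8-fold changes were recovered in 26.9% and 53.0% of cases.

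Leaving out Noggin and R-Spondin-1 was tested within differentiation medium (2 against 2). It called 0 genes by edgeR (260 at an unadjusted p under 0.05, smallest adjusted p 0.726), by DESeq2 and by voom. By value, KRT10 changed by 0.28, IVL by 0.29, KRT14 by 0.11, KRT15 by -1.83 (299.6 against 1061 CPM), ID1 by 0.17, SLC2A1 by -1.59 (121.3 against 361.8 CPM) and KRT19 from 24.0 to 0 CPM. The glycolysis list lay lower (median -0.44, adjusted p = 0.000631, adjusted p = 0.923 with an estimated correlation) with 0 of 25 called. Leaving out Forskolin as well (2 against 2) also called 0 genes by edgeR (328 at an unadjusted p under 0.05), by DESeq2 and by voom, and the interferon list lay higher (median 0.74, 0.0382, adjusted p = 0.969 with an estimated correlation) with 0 of 12 called, OAS1 standing at 210.9 against 55.6 CPM. Libraries with the same replicate number resembled each other, with deviations of replicate 1 correlated by 0.466 to 0.593 between media. With the number as a block within these media both comparisons also called 0 genes (243 and 304 at an unadjusted p under 0.05). Without a filter on low counts the comparisons called 12 and 20 genes. Simulated 8-fold changes were recovered in 56.1% and 40.9% of cases and 4-fold ones in 26.9% and 16.4%.

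The fully depleted differentiation medium was compared with expansion medium (2 against 2). Of 12 interferon response genes 3 were called higher, though the list lost its call with an estimated correlation: ISG15 by 6.39 ± 0.88 (166.4 against 2.04 CPM, adjusted p = 0.00123), IFI44 by 4.09 and OAS1 by 3.63. CLDN4 rose by 6.13, the elastase inhibitor PI3 by 5.30 (3090 against 78.8 CPM), KRT7 by 3.56 and the Tgf-beta targets THBS1 by 3.38, ITGAV by 1.75 and PMEPA1 by 2.11 (147.8 against 33.0 CPM). CD9 (-2.47), GAPDH (-2.08) and IDI1, an enzyme of isoprenoid synthesis (-2.72), fell, and KRTAP3-1, which stood at the carry-over level in expansion medium, was at least 42.3-fold lower. Of the interferon list 3 of 12 rose (4 adjusted over the list alone; median 2.04, camera adjusted p = 4.23e-05, adjusted p = 0.136 with an estimated correlation), and of the Tgf-beta target list 3 of 34 (5 rose and 1 fell adjusted over the list alone; 0.152). Of the cholesterol list 1 of 22 fell (5 adjusted over the list alone; 0.0026, adjusted p = 0.717 with an estimated correlation), and the G2 list lay lower (median -0.98, 0.0026, adjusted p = 0.717 with an estimated correlation) with 0 of 28 called. The hair list had 2 of 20 lower (8 adjusted over the list alone; 0.0144, adjusted p = 0.717 with an estimated correlation; median -4.56, or -0.67 at the bounds).

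**Figure D4:**
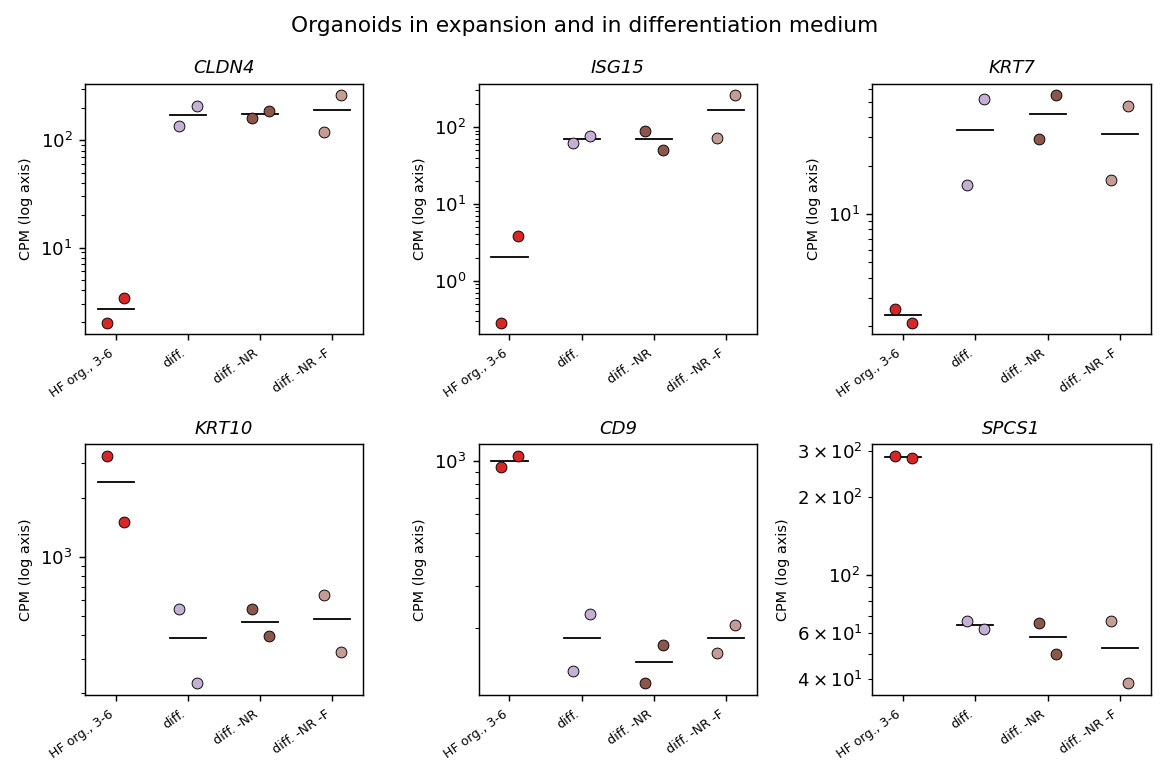
CPM (log y axis) of 6 genes in later follicle-derived organoids in expansion medium, in differentiation medium, and in it without Noggin and R-Spondin-1 and also without Forskolin (x axis), with a point per library and a line at each group mean. CLDN4, ISG15 and KRT7 lie higher, and KRT10, CD9 and SPCS1 lower, in all 6 differentiation libraries than in the 2 in expansion medium.

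This comparison called 97 genes higher and 224 lower, 58 and 131 in all without expansion replicate 1 and 2, 8 without differentiation replicate 2, and 0 in a fit to these groups alone, and 0 of 28 named genes kept their call in every setting run. By DESeq2 size factors the split was 146 and 180 and the median of all genes 0.00 in place of -0.13. Simulated 4-fold and 8-fold changes were recovered in 31.3% and 65.2% of cases.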

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

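No test in this part was chosen after its result was seen. The effect of the Tgf-beta inhibitor on follicle-derived organoids differed between early and later passage in 6 of the gene lists by camera's test of the interaction, while 0 single genes passed it, and every one of these calls was lost with an estimated correlation.

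The inflammatory cytokine list had a less positive effect at later passage (median difference -1.68, adjusted p = 2.12e-06, adjusted p = 0.226 with an estimated correlation). CXCL8 differed by -4.71 and PTGS2 by -2.34, and 3 of 6 members passed when adjusted over the list alone. The wound and hyperproliferation list differed in the same direction (median -2.18, adjusted p = 1.4e-05, adjusted p = 0.604 with an estimated correlation), as did the basal keratinocyte list (-0.44, adjusted p = 0.0223, adjusted p = 0.626 with an estimated correlation).

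The fibroblast and dermal papilla list had a more positive effect at later passage (median 0.68, adjusted p = 0.000291, adjusted p = 0.604 with an estimated correlation), with DCN at 2.51 and VIM at 2.60, the 2 members that passed when adjusted over the list alone. The Wnt and R-spondin target list (0.63, adjusted p = 0.0305, adjusted p = 0.604 with an estimated correlation) and the mitochondrially encoded list (0.36, adjusted p = 0.0223, adjusted p = 0.821 with an estimated correlation) went the same way. Single early libraries stand apart in genes of the fibroblast list and of other lists: VIM was at 134.7 CPM in early replicate 1 without the inhibitor against 28.2 in replicate 2, IVL was at 24318 CPM in early replicate 1 with the inhibitor, and TYRP1 at 229 and KRT10 at 13104 CPM in early replicate 1 without it.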

How the results depend on the processing

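The fits to one passage and without genes at the carry-over level were chosen after seeing the data. The 15 counts of called genes stayed within 1.5 times of their value, or at 0, under voom, DESeq2 size factors, library totals and the stricter filter, and those rerun without genes at the carry-over level did so too. The split of these totals into higher and lower genes was less stable. By library totals it reversed for interfollicular organoids against tissue and for the inhibitor early. Of 437 called genes named in a comparison, 134 kept their call in every setting run for them and 303 lost it at least once, of 35 settings. The sign changed for 2: TYRP1 in the early inhibitor comparison ran from -5.18 to 0.14 with each replicate left out, the latter without early replicate 1 lacking the inhibitor, and KREMEN1 in interfollicular against follicle-derived organoids at -0.12 with early libraries alone. Where no cause is given, the cause was not tested.

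Without a filter on low counts the comparisons called 478 genes for follicle against interfollicular tissue, 2 for follicle and 285 for interfollicular tissue against skin, 639 for the inhibitor, 506 early and 155 later, 171 for passage, 39 for the interaction, 642 for differentiation medium, 613 for the depleted medium against expansion, 12 for leaving out Noggin and R-Spondin-1 and 20 for leaving out Forskolin. With counts thinned to the smallest library, which removes counts by construction, they were 153 for follicle against interfollicular tissue, 587 and 505 for follicle-derived and interfollicular organoids against tissue, 31 for the inhibitor, 7 early and 2 later, 2 for passage, 230 for interfollicular against follicle-derived organoids, 18 for differentiation medium and 25 for the depleted one. Against a fold of 1.5, a stricter hypothesis, they were 171 for the tissues, 95 for the inhibitor, 36 early and 13 later, 12 for passage, 123 for differentiation medium and 127 for the depleted one.

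The DESeq2 Wald test called 207 genes for the inhibitor early, 59 for passage, 1 for the interaction, 531 for differentiation medium and 572 for the depleted one. Fits to the compared groups alone, with fewer libraries behind the spread, called 465 genes for the tissues, 10 for follicle against skin, 0 for the inhibitor early and 82 later, 21 for passage, 1 for differentiation medium and 0 for the depleted one. Early libraries alone gave 709 genes for interfollicular organoids against tissue and 60 against follicle-derived organoids. Of 416 gene list tests, 127 were called with the preset correlation, 17 with an estimated correlation and 61 by fry.

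The values showed little sign that replicate numbers pair the tissue or the expansion samples. Replicate 1 deviations correlated across genes by 0.03 to 0.16 between tissue groups and -0.31 to 0.13 between expansion groups. Those of the differentiation groups correlated more (0.47 to 0.59), and either block gave 0 genes between these groups. The labels do not say what the numbers stand for, so a shared culture and a shared run cannot be told apart. With the replicate number as a block over all groups the counts were 67 for the inhibitor early, 19 later, 18 for passage, 206 for differentiation medium and 209 for the depleted one. With the replicate block nested in the kinds of samples they were 425 for the inhibitor, 239 early, 66 later and 58 for passage. The nested block was not run where sample kinds are compared, since it cannot be estimated there.

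With each replicate left out in turn the counts ran from 113 to 170 for the tissues and 64 to 109 for interfollicular tissue against skin, from 1389 to 2954 and 416 to 914 for follicle-derived and interfollicular organoids against tissue, from 109 to 303 for the inhibitor, 9 to 174 early and 3 to 11 later, from 9 to 53 for passage, from 12 to 370 for differentiation medium and from 8 to 352 for the depleted one. A library left alone in its group was assumed to vary like the other groups, and the interfollicular organoid libraries were not left out, since each is a whole group. Depth limits the epidermis most: at 86301 counts its smaller library leaves open levels of up to 35.5 CPM for a gene at 0.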

Other observations

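The gene groups in the first paragraph, and the tests of the hair transcripts and of the genes higher in interfollicular organoids, were chosen only after the results were seen. Among 12 tested metalloproteinases and their inhibitors, 3 rose and 0 fell with the Tgf-beta inhibitor (4 and 3 adjusted over the group alone): MMP1, a collagenase, by 3.40 ± 0.53 (1925 against 243 CPM, adjusted p = 0.000846), MMP3, a stromelysin, by 4.54 (39.1 against 1.78 CPM), and TIMP1, while MMP13 did not pass (-2.72, adjusted p = 0.0705). MMP1 stood at 1365 ± 916 CPM (SD, n = 3) early and 2484 ± 619 later with the inhibitor, and at 71.5 ± 47.8 and 414.6 ± 229 without it. Among 5 tested cyclin-dependent kinase inhibitors, with a median of -0.83, 1 rose and 0 fell with passage (1 and 2 adjusted over the group alone). The 1 that rose was CDKN2A, which halts the cell cycle and marks senescence (2.69 ± 0.51, 223.9 against 32.5 CPM, adjusted p = 0.0152). At later passage it stood at 315.8 ± 6.42 CPM with the inhibitor and 131.9 ± 127 without it. Of 23 tested genes of the signal peptidase, translocon and oligosaccharyltransferase, which process proteins entering the secretory pathway, 7 fell in differentiation medium and 1 rose (8 and 2 adjusted over the group alone), and 7 fell in the depleted medium. SPCS1 was at -2.13 (64.6 against 284.5 CPM, adjusted p = 0.00304), OSTC at -3.28 (6.81 against 66.8 CPM) and SEC61A1, the one that rose, at 1.42. These group medians kept their sign under both other scalings. The calls of CDKN2A and of the signal peptidase, translocon and oligosaccharyltransferase genes were not followed with libraries left out. In the passage comparison, 0 of 13 named genes kept their call in every setting run. Both differentiation comparisons lost most of their calls without differentiation replicate 2.

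Hair-shaft transcripts were present in every expansion library and highest in the interfollicular ones. Follicle cells left over from the isolation are argued against, since the lowest share at passages 3 to 6 was 0.706 of the highest at passages 0 to 1, with means of 0.95% and 0.973% of the tissue level. A candidate explanation is RNA of whole tissue carried into these libraries: over the 9 follicle-derived libraries, 23 abundant markers of immune, vascular, muscle, fat and pigment cells stood at a median of 1.61 times the hair-list share, from 0.701 to 5.71. In the later interfollicular library the other markers stood at a median of 13% of the tissue level and the hair list at 12.4%, similar shares that carried RNA alone could give. Relative to the follicle-derived libraries the other markers were raised 6.34 times (quartiles 1.45 and 14.7) and hair genes 12 times. Those libraries held the other markers at 0.703 to 4.93% and the hair list at 0.704 to 1.26%. Hair-shaft differentiation in the organoids stays open, because a mixture of carried RNA and differentiation could also give these values. Whether carried RNA came from dissection, sorting or sequencing was not tested.

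More genes were higher in interfollicular than in follicle-derived organoids than the reverse, 578 against 51. Of the 578, 79 (13.7%) stood at the level of carried tissue RNA, a larger share than the 862 of all 9888 genes tested. The 79 called genes at that level were all higher. Carried RNA as the only source of the transcripts is thus argued against for most of the 578. That does not show what raised them. The level is a mean over both kinds of organoid, so how much carried RNA added to genes that the organoids express was not tested. A difference kept from the tissues is argued against as the main source, but not excluded. Of the 578, 40.5% (95% Clopper-Pearson interval 36.5 to 44.6%) were higher in interfollicular tissue, against 40.4% of all genes tested. The 578 include the 79 genes at the carried level, which was taken from follicle and skin tissue, and the test was not repeated without them. Direction in the tissues also rests on 2 interfollicular libraries of 86301 and 335949 counts. The single later library remains a possible cause: the genes called higher in the later pair had a median of 0.78 in the early pair (quartiles 0.22 and 1.46, all genes -0.16), so that the median lay above and the lower quartile below the bound of 0.25 set for the test. Each pair holds 1 interfollicular library, so the spread behind its calls comes from the groups with replicates. Of the 51 genes higher in follicle-derived organoids, 29 (56.9%, interval 42.2 to 70.7%) were higher in follicle tissue, against 59.1% of the other genes (one-sided Fisher's exact p = 0.68), and 0 were also called there. That leaves open whether this smaller set keeps any trace of its source.

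Chance is argued against, but not excluded, for both comparisons of the 9 follicle-derived expansion libraries, by a wide margin for the inhibitor and a narrow one for passage. Of 60 splits within passage, 1, the real split by inhibitor, called as many as its 310 genes, and the highest other split called 7. Of 60 splits within the inhibitor groups, 1, the real split by passage, called as many as its 21 genes, and the highest other called 14. These fits used the 9 libraries and 9417 genes. A share of 1 in 60 is the smallest that such splits can give, and they treat the libraries as independent, which the labels do not state. The passage count also depends on single libraries.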
